A study of Chlamydomonas reinhardtii with 6 samples.

How the data were processed

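Poly-A RNA was sequenced on the Illumina HiSeq platform from 6 cultures of Chlamydomonas reinhardtii CC-4532, 3 with 6 µM and 3 with 1000 µM manganese, per the labels' protocols. Cultures of 1 L were started at 10000 cells per mL, shaken at 180 rpm at 24 °C under about 50 µmol of photons per square metre and second, and harvested at 3000000 cells per mL. The design text describes 6 flasks inoculated from a starter culture, so the replicates are separate cultures of 1 strain that share an inoculum, and p-values measure the spread between such cultures. The group and number of each sample were taken from its title, and each column of the table was assigned to the sample whose title gives the same manganese level and replicate number. No per-sample column was left unused. The groups rest on these labels, and no measurement in the table checks them independently, so a mislabelled library would change the group means and differences.

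The authors deposited 1 table of FPKM values per gene and library. CASAVA, STAR and Cuffdiff 2.2.1 are named in the submitters' processing notes. Their settings, the genome build used for alignment, any filter and the normalization option are not given in the sources used here. The FPKM sums of the deposited libraries ranged from 629620 to 767912, and each library's median over tested genes lay between 6.09 and 6.27 FPKM. FPKM values do not carry the depth, so no counting interval or detection floor can be given, and a value of 0 may be an estimate that failed: a gene is said only to be listed at 0. Among genes with a mean under 0.15 FPKM, the ratio of the values in 2 libraries piled up at single positions, as whole reads would give. Between 13.7% and 16.4% of such genes lay within 0.01 log2 units of the most frequent ratio to 6 µM replicate 1, and these ratios gave the relative number of reads per FPKM. They include whatever scaling the authors applied. Read counts were not reconstructed, because the value of 1 read also depends on each gene's length, and no count model was run. Multi-copy and overlapping genes are uncertain where the counting could divide reads between them, and the strand setting is not given in the sources used here.

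The identifiers carry the version v5.5 and were matched by locus tag to a RefSeq gene table of assembly Chlamydomonas_reinhardtii_v5.5, with 17738 of 17741 matched and 3 not. Positions are those of this assembly, whatever build the reads were aligned to. The table gave chromosome, start and end (1-based), and no symbols or synonyms (0 matched genes had either). The gene lists fixed before the data were examined, on metal homeostasis, nutrition, photosynthesis, stress and growth, were written as symbols. They could therefore not be matched, and the list tests were not run. The naming rule fixed at the same time took genes past an adjusted p of 0.05 with non-overlapping groups, plus members of those lists and a set of symbols for metal transport and photosynthesis. It named no gene, so the 2 genes with the smallest p in each direction are given instead.

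Values were transformed to log2(FPKM + 1), so that differences of low genes are understated, and genes with a mean of at least 1 FPKM over all 6 libraries were kept. Differences between 1000 µM and 6 µM manganese were tested two-sided with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with a mean-variance trend), with Benjamini-Hochberg adjustment over 12543 genes and a threshold of 0.05. Intervals are at the 95% level from the moderated standard errors. The test was checked on simulated data: in 20 runs with 200 changed genes, 4.34% of its calls were false when genes varied independently, and 26.7% when they shared a random library axis of the size seen here. The simulated axis took a random direction and could lie along the manganese grouping, whereas the axis it copies was taken within groups. The 26.7% is therefore not the false share of this comparison. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

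Alternatives fixed before the data were examined were pseudocounts of 0.1 and 5, no filter and a minimum mean of 5 FPKM, scaling to the same total, quantile normalization and median-of-ratios scaling, a replicate block, eBayes without a trend or robust, library quality weights, Spearman correlation, and leaving out each library in turn. The first component of the residuals as a covariate, and leaving out both libraries that stood apart, were added after seeing the data. No batch is given in the labels.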

Results

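The transcriptome of the unicellular green alga Chlamydomonas reinhardtii, strain CC-4532, was compared between cultures grown with 1000 µM manganese and cultures grown with 6 µM manganese, the level the labels call the control. Manganese is a micronutrient needed for the oxygen-evolving centre of photosystem II and for Mn superoxide dismutase, and the comparison addresses how the poly-A RNA pool differs when the metal is supplied in excess. There were 3 flasks per group, all inoculated from a starter culture in acetate-containing medium, grown under continuous light at 24 °C and harvested at 3000000 cells per mL, in mid-logarithmic growth. The deposited table gave FPKM values, in which fragment counts are scaled to transcript length and library size, for 17741 gene models in the 6 libraries. Its identifiers carry the v5.5 gene-model version and no gene symbols, and the reference table that matched 17738 of them holds no symbol or synonym for any, so the genes are given here by identifier and position, and no function is assigned to them.

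The absolute sequencing depth of the libraries is unknown, because FPKM values do not keep it. The relative depth could be read from the steps between low values, which differ by whole reads. Taking 6 µM replicate 1 as 1, the number of reads behind 1 FPKM was 1.08 in 6 µM replicate 2 and 1.12 in 6 µM replicate 3. It was 1.03, 0.713 and 0.851 in 1000 µM replicates 1, 2 and 3. Between 16052 and 16230 genes had a value above 0 per library, and the 10 most abundant genes held 10.4% to 11.5% of the summed FPKM. A mean of at least 1 FPKM over the 6 libraries was reached by 12543 genes, and these were tested.

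No gene differed between 1000 µM and 6 µM manganese at an adjusted p under 0.05 in limma's moderated test with Benjamini-Hochberg adjustment, and the smallest adjusted p was 0.0778. At an unadjusted p under 0.05 there were 354 genes, 135 higher and 219 lower at 1000 µM, where 627 would be expected by chance from independent genes. In the same test with each library scaled to the same FPKM total, 2 genes passed, both lower, and at an unadjusted p under 0.05 the counts were 37 higher and 493 lower. With library quality weights 26 genes passed, 25 of them lower. Those weights were 6.58, 0.884 and 0.267 for 1000 µM replicates 1, 2 and 3, so that group's mean rested mainly on 1 library. Without 6 µM replicate 1 there were 2 genes at the adjusted threshold and without 1000 µM replicate 3 there was 1, all lower. The log2 difference lay within 0.5 of 0 for 99.4% of the tested genes, and its SD across genes was 0.13.

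The genes with the smallest p-values were lower at 1000 µM manganese. The 22 smallest p-values all belonged to genes with a lower mean at 1000 µM, and each of the 18 genes with an unadjusted p under 0.001 was lower in all 3 libraries at 1000 µM than in any library at 6 µM. Their differences of log2(FPKM + 1) ran from -1.48 to -0.47, with a median of -0.64. Their mean levels at 6 µM were between 1.605 and 27.4 FPKM, and for the low ones this scale understates the fold of FPKM. The gene at -1.48 averaged 2.4 ± 1.6 FPKM at 6 µM and 0.14 ± 0.12 FPKM at 1000 µM (SD, n = 3 each). It was listed at 0 in 1000 µM replicate 2, so its fold is uncertain. Chance alone would put about 12.5 of 12543 independent genes below that p. None of the 18 passed the adjusted threshold. The count at that p was 31 without 6 µM replicate 2, with 6 of them higher, and 30 without 1000 µM replicate 3. It was 10 without 6 µM replicate 3 and 7 without 1000 µM replicate 1.

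No gene met the rule for naming genes that was set before the data were examined, which required an adjusted p under 0.05 or a listed gene symbol. The 4 genes named here, the ones with the smallest p in each direction, were chosen after their values were seen. Cre02.g107550.v5.5, on chromosome 2 from 5432380 to 5436217, averaged 14.5 ± 1.76 FPKM (SD, n = 3) at 6 µM and 6.59 ± 0.225 FPKM (SD, n = 3) at 1000 µM. Its log2 difference was -1.02 with a standard error of 0.11 (limma adjusted p = 0.0778). Cre03.g150750.v5.5, on chromosome 3 from 1335097 to 1338359, averaged 5.60 ± 0.813 FPKM (SD, n = 3) at 6 µM and 2.32 ± 0.118 FPKM (SD, n = 3) at 1000 µM. Its log2 difference was -0.98 with a standard error of 0.11 (limma adjusted p = 0.0778). Without 6 µM replicate 1, both passed the threshold with a limma adjusted p of 0.0457, in a range of 0.00102 to 0.883 over the alternatives. Among genes with a higher mean at 1000 µM, Cre12.g554350.v5.5, on chromosome 12 from 7664021 to 7668392, averaged 28.1 ± 0.471 FPKM at 6 µM and 39.3 ± 2.67 FPKM at 1000 µM (SD, n = 3 each). Its log2 difference was 0.47 with a standard error of 0.10 (limma adjusted p = 0.657). Cre02.g115226.v5.5, a short gene model on chromosome 2 from 6338125 to 6338481, averaged 3.097 ± 0.589 FPKM at 6 µM and 4.96 ± 0.161 FPKM at 1000 µM (SD, n = 3 each), a log2 difference of 0.55 with a standard error of 0.12 (limma adjusted p = 0.657). For each of the 4 genes the libraries of one group all lay above those of the other. This also held for 1008 of the tested genes (8.04%), where chance gives 10% for 3 against 3.

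**Figure D1:**
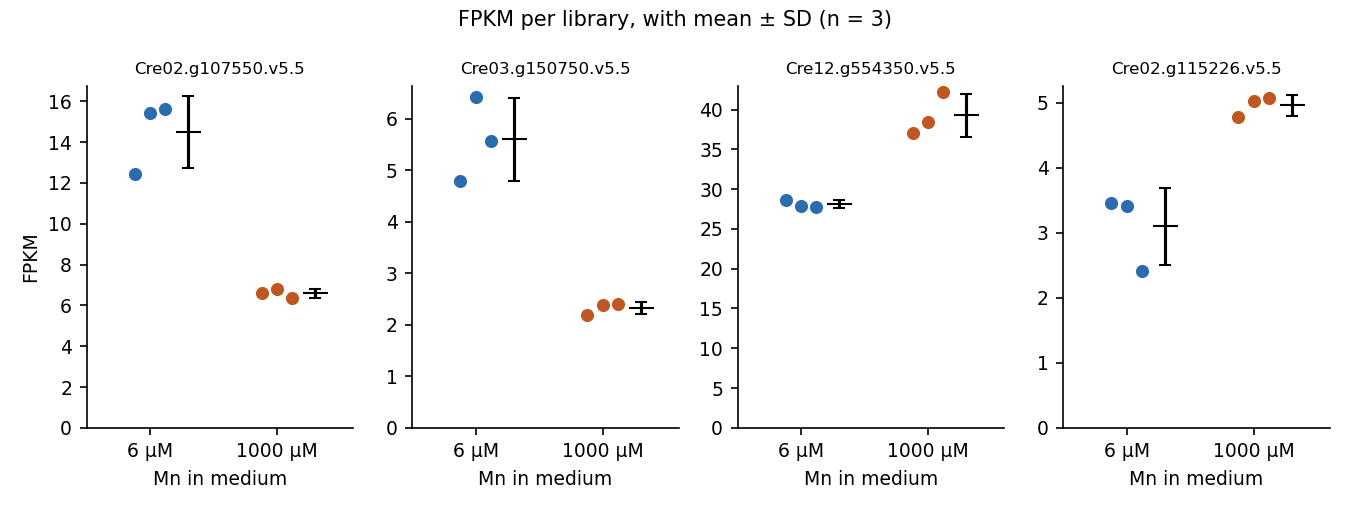
FPKM (vertical axes, starting at 0) of the 4 genes with the smallest p in each direction, with 1 point per library and the mean ± SD (n = 3) beside each group at 6 µM and 1000 µM manganese. The 2 genes on the left averaged 14.5 and 5.60 FPKM at 6 µM against 6.59 and 2.32 FPKM at 1000 µM, and none of the 4 reached an adjusted p under 0.05.

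Of 44 genes with an unadjusted p under 0.005 and a lower mean at 1000 µM, 5 lay between positions 178950 and 520575 of chromosome 11, a segment that was singled out after its values were seen. Their log2 differences ran from -0.82 to -0.56. The gene from 473142 to 474946 averaged 15.3 ± 1.88 FPKM at 6 µM and 8.55 ± 0.797 FPKM at 1000 µM (SD, n = 3 each), and its neighbour from 470916 to 472941, 200 bp away, averaged 15.4 ± 4.41 and 8.24 ± 2.205 FPKM. The gene from 518778 to 520575 averaged 6.20 ± 0.310 FPKM at 6 µM and 3.63 ± 0.262 FPKM at 1000 µM. The other 33 tested genes of the segment had a median log2 difference of -0.002, with quartiles at -0.08 and 0.06. None of the 5 passed the adjusted threshold over all genes, and the smallest limma adjusted p among them was 0.173.

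**Figure D2:**
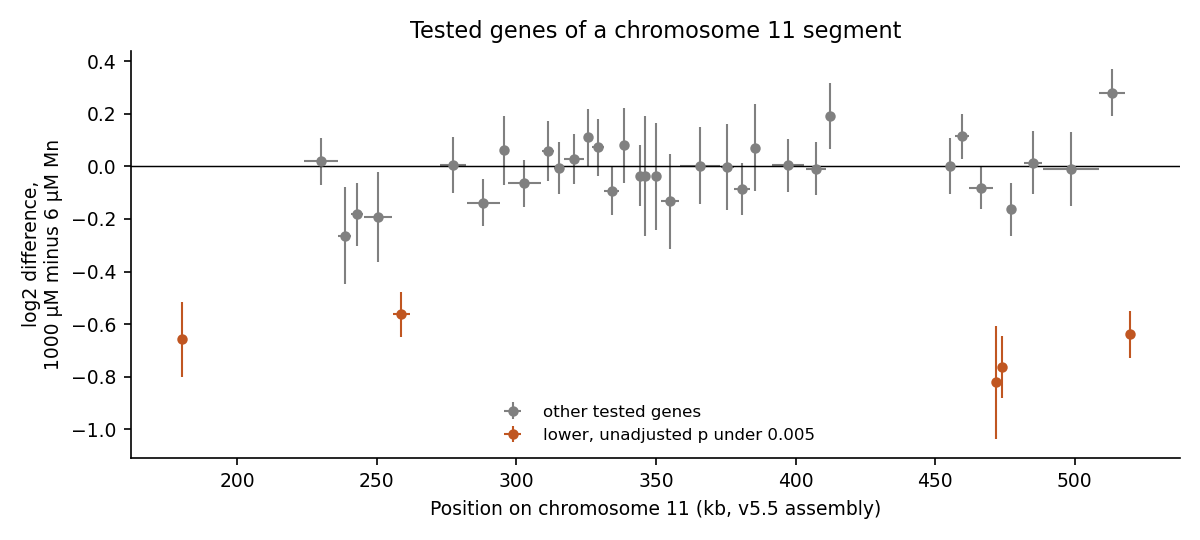
Log2 difference between 1000 µM and 6 µM manganese (vertical axis, bars ± 1 standard error) of the 38 tested genes from 178950 to 520575 on chromosome 11 of the v5.5 assembly (horizontal axis, kb; horizontal bars span each gene). The 5 genes in orange lie between -0.82 and -0.56 and are interspersed with 33 genes between -0.26 and 0.28.

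The size of change that the 3 cultures per group can exclude was taken from the 95% confidence intervals of each gene, unadjusted for the number of genes. Intervals on the log2(FPKM + 1) scale were set against the change in that scale that a given fold of FPKM makes at each gene's 6 µM level. For 12268 genes (97.8%) the interval lay inside a 2-fold change of FPKM in either direction, and for 10205 genes (81.4%) inside a 1.5-fold change. With no filter on low values, the former share was 83.3%. The median half-width of the interval was 0.26 on the log2(FPKM + 1) scale. In simulated data for this comparison, built on the spread of the 12543 genes, 200 genes were changed. Where genes varied independently, the same test called 71.3% of genes changed 2-fold, 91.9% of those changed 3-fold and 32.3% of those changed 1.5-fold. Where genes shared a random library axis, these shares were 72.0%, 92.6% and 27.2%, and 26.7% of all calls were false against 4.34%. That axis could lie along the manganese grouping, unlike the within-group axis it copies, so 26.7% is not the false share here. With fewer changed genes the adjusted threshold is stricter, so the shares of changed genes called do not carry over to data with few changes.

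Cultures of the same manganese level were no more alike than cultures of different levels. Across the 12543 genes, log2(FPKM + 1) values correlated between libraries with Pearson's r from 0.982 to 0.996, a description across genes, which are not independent replicates. The mean r was 0.9905 within groups and 0.9913 between groups. The closest partner of 6 µM replicate 1 was 1000 µM replicate 3, with r = 0.9947, while 6 µM replicate 1 correlated with 6 µM replicates 2 and 3 at 0.9885 and 0.9919. The first principal component held 57.8% of the variance and set these libraries, with scores of 0.110 and 0.222, apart from the other 4, which scored between -0.115 and -0.033.

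**Figure D3:**
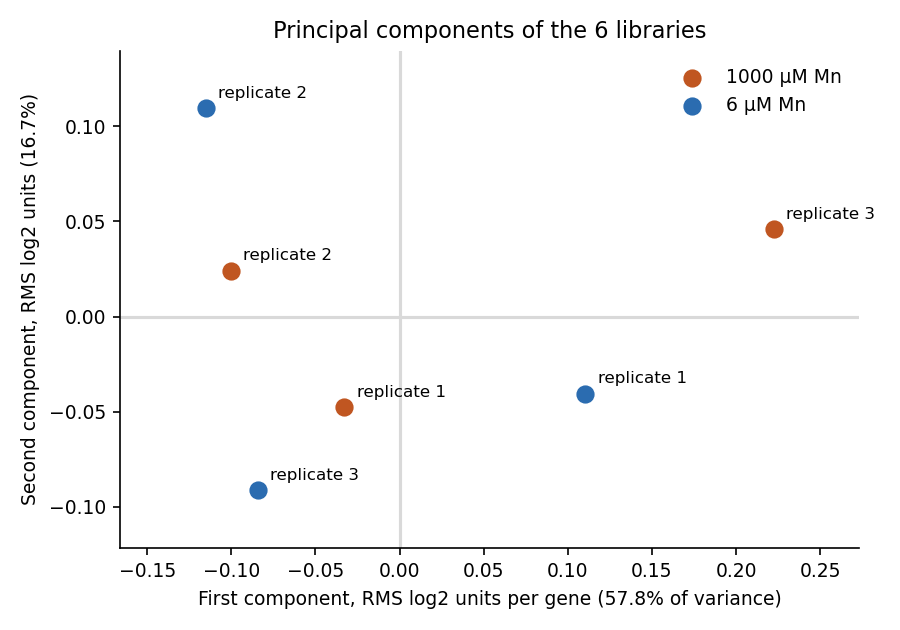
Scores of the 6 libraries on the first component (horizontal) and the second component (vertical) of log2(FPKM + 1) over 12543 genes, in root-mean-square log2 units per gene, coloured by manganese level, with 1 point per library. The libraries 6 µM replicate 1 (0.110) and 1000 µM replicate 3 (0.222) lie to the right of the other 4, and the colours are mixed along the horizontal axis.

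The pair of libraries that stood apart on the first component came from different manganese levels, so the size of the difference was also read inside that pair and among the other 4, with its sign fixed beforehand by the choice of genes whose groups do not overlap. For Cre02.g107550.v5.5 the log2 difference was -0.87 within the pair and -1.10 among the other 4 libraries, and for Cre03.g150750.v5.5 it was -0.77 and -1.09. For Cre12.g554350.v5.5 it was 0.54 and 0.43, and for Cre02.g115226.v5.5 it was 0.45 and 0.60. With both libraries of the pair left out, an alternative chosen after seeing the data, limma called 3 genes at an adjusted p under 0.05, all lower at 1000 µM, and 638 genes at an unadjusted p under 0.05.

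**Figure D4:**
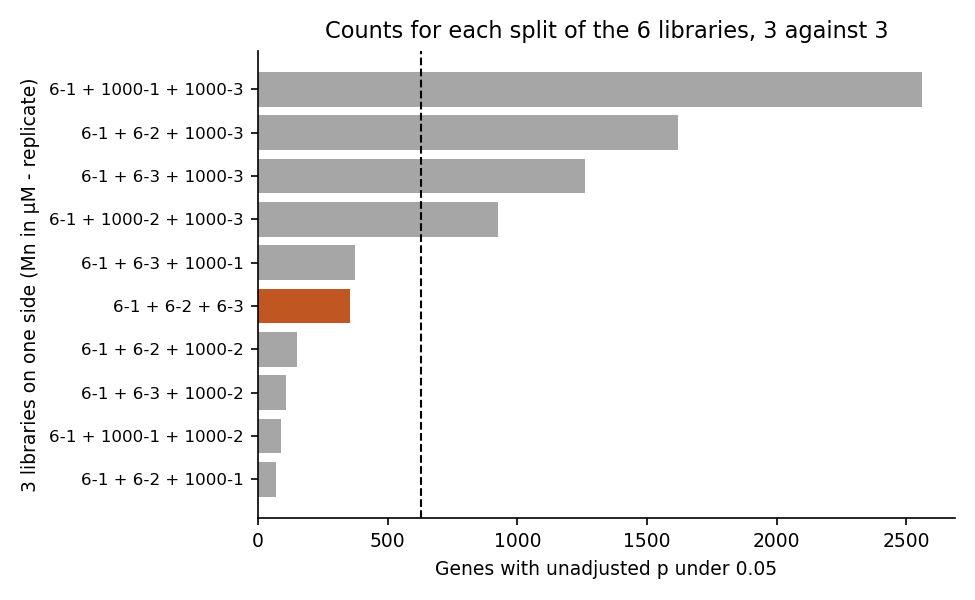
Number of genes with an unadjusted p under 0.05 (horizontal axis) for each of the 10 ways to divide the 6 libraries 3 against 3, labelled by the libraries on one side, with the manganese comparison in orange and the count expected by chance from independent genes (627) as a dashed line. The manganese comparison gave 354 genes, and the 4 splits that put 6 µM replicate 1 and 1000 µM replicate 3 on the same side gave 926 to 2559.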

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

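The residual-component covariate and the omission of both libraries that stood apart were chosen only after the data were seen. That component comes from the residuals of the same fit. It leaves each log2 difference unchanged and takes up residual spread, which tends to lower p-values by construction. The count of 0 genes at an adjusted p under 0.05 held in 13 of 19 alternatives. It became 26 (1 higher, 25 lower) with library quality weights, which gave 1000 µM replicate 1 a weight of 6.58 and 1000 µM replicate 3 a weight of 0.267, and 2 with the same FPKM total per library. It became 21 (2 higher, 19 lower) with the first residual component as a covariate, and 3 with 6 µM replicate 1 and 1000 µM replicate 3 both left out. The settings with weights and with the residual component called 15 genes in common. Leaving out single libraries gave 0 to 2 genes: 2 without 6 µM replicate 1, 1 without 1000 µM replicate 3 and 0 without any of the other 4. The 354 genes at an unadjusted p under 0.05 became 618 with no filter, 172 at a minimum mean of 5 FPKM (88 higher, 84 lower), 1272 with quality weights, 1519 with the residual component and 638 without both libraries. They numbered 251 to 496 when 1 library was left out. The 18 genes at an unadjusted p under 0.001, all lower, became 6 at a minimum mean of 5 FPKM and 34 without both libraries, again all lower. They became 82 with quality weights (20 higher, 62 lower), 70 with the residual component (15 higher, 55 lower) and 26 with no filter (6 higher, 20 lower). They numbered 7 to 31 with 1 library left out, with 10 without 6 µM replicate 3, 7 without 1000 µM replicate 1, 31 without 6 µM replicate 2 and 30 without 1000 µM replicate 3. Deviations of same-numbered libraries from their group means correlated at -0.40, 0.51 and -0.50 across genes for numbers 1, 2 and 3, so the numbers were not treated as pairs, and not every library correlated best with its own number. With a replicate block the counts were 0 at the adjusted threshold, 306 at p under 0.05 and 17 at p under 0.001 (5 higher, 12 lower). The cause of these shifts was not tested. Scaling to the same total moved the median log2 difference of all tested genes from 0.01 to -0.06. The difference between the mean correlation within and between groups was -0.0008 and stayed between -0.0017 and 0.00012 in 15 alternatives. Cre02.g107550.v5.5 and Cre03.g150750.v5.5 kept their direction in every alternative that tested them and passed the limma adjusted threshold in 5 each, with adjusted p from 0.00102 to 0.883. Cre12.g554350.v5.5 and Cre02.g115226.v5.5 kept their direction and never passed (at least 0.0547 and 0.0526). The list tests were not run for want of symbols, nor the count-based ones on FPKM values. The unknown depth limits statements on genes under 1 FPKM.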

Other observations

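The tests on depth, on chromosome 11, on splits of the libraries and on the omission of both libraries that stood apart, the classes of abundance and the residual-component covariate were chosen only after the results were seen.

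Counts by class of abundance are given as values, with no test of the difference between classes. Among 677 genes with a mean of at least 100 FPKM, 16 had an unadjusted p under 0.05 with a higher mean at 1000 µM and 0 with a lower one, and the median log2 difference was 0.09. Among 5394 genes between 1 and 5 FPKM the counts were 50 higher and 134 lower, with a median of -0.02. In both classes these are fewer genes than the 5% that chance gives among independent genes. With the same FPKM total per library the abundant class had 5 higher and 6 lower, with a median of 0.0013, and the low class had 17 higher and 291 lower, with a median of -0.08. Under median-of-ratios scaling the abundant class had 15 higher and 0 lower, with a median of 0.08. The low class had 46 higher and 136 lower, with a median of -0.02. The factors of that scaling lay between 0.994 and 1.014, so it changed the values little. After quantile normalization the abundant class had 10 higher and 8 lower, with a median of -0.0081. The low class then had 78 higher and 108 lower, with a median of 0.0058. On the values as deposited, the groups overlapped in the low class. The median deviation of a library from the gene means there was -0.0078, 0.0091 and 0.028 in 6 µM replicates 1, 2 and 3. In 1000 µM replicates 1, 2 and 3 it was 0.0062, 0.0036 and -0.039. The lowest of these belongs to 1000 µM replicate 3, which stood apart on the first component. In the abundant class the deviations were -0.070, 0.0021 and -0.062 at 6 µM and 0.010, 0.079 and 0.053 at 1000 µM.

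A small number of genes were listed at 0 throughout one group. At 6 µM, 9 genes were listed at 0 in all 3 libraries and above 0 in all 3 at 1000 µM, with means of at most 0.0427 FPKM. At 1000 µM, 16 genes were listed at 0 in all 3 libraries and above 0 in all 3 at 6 µM, with means of at most 0.116 FPKM. All lay below the level at which genes were tested. The counts of 9 and 16 are not compared, because the relative depth differed between the groups. In 1000 µM replicates 2 and 3 it was 0.713 and 0.851 reads per FPKM, below every 6 µM library.

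The libraries 6 µM replicate 1 and 1000 µM replicate 3 shared a deviation from their groups: across genes, their deviations from the group means correlated at 0.752. After removing a smooth trend with gene span and expression level the correlation was 0.744, which argues against such a trend as its source. It was 0.741 without the tenth of genes that were most abundant, so it did not rest on them. After quantile normalization it was 0.744, which argues against differing distributions of values. Scaling by a single factor per library shifts all genes of that library nearly alike, so it can hardly produce a correlation across genes. What it leaves through the added 1 depends on expression level. The correlation of 0.744 after removing the trend with level argues against that part too. Depth stays open: 1 of the other 4 libraries, 1000 µM replicate 2 at 0.713 reads per FPKM relative to 6 µM replicate 1, was shallower than both and scored -0.100 on the first component, while the pair stood at 0.851 and 1 and the other 3 at 1.03 to 1.12. A mislabelled library, which would change every group mean and difference given here, and a state of the cultures or of RNA preparation that the labels do not record were not tested and stay open too. No biological explanation of the shared deviation was tested.

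The 18 genes with an unadjusted p under 0.001 were all lower at 1000 µM manganese. Scaling is argued against as the source of this one-sidedness by quantile normalization, after which 1 of 18 genes at that p (5.56%) was higher. Median-of-ratios scaling gave 0 of 20, but its factors of 0.994 to 1.014 left the values nearly unchanged, so it tests little. With the same FPKM total per library 0 of 23 were higher. That scaling moved the counts at an unadjusted p under 0.05 to 37 higher and 493 lower. For the library axis, with 6 µM replicate 1 and 1000 µM replicate 3 both left out, 34 genes reached that p and 0 of them were higher, which argues against it as the whole source. Not every setting was as one-sided: 15 of 70 genes at that p were higher with the first residual component as a covariate, 20 of 82 with library quality weights and 5 of 17 with a replicate block. Between 1000 µM replicate 3 and 6 µM replicate 1 the 18 genes had a median log2 difference of -0.64, a value whose sign is fixed because the groups of all 18 do not overlap. Of the 10 splits of the 6 libraries 3 against 3, 2 gave as many genes at that p, the real one included, with 18 in the real split and 30 in the highest of the others, and 10 splits are too few for a share under 0.05. That highest split puts 6 µM replicate 1 and 1000 µM replicate 3 on the same side, and the 5 other splits that part them, as the real one does, gave 0 to 3. A response of some of these genes to 1000 µM manganese may lie behind the pattern, which remains a hypothesis found and tested on the same data.

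The counts at the other thresholds gave the following over the same 10 splits, which are too few for a share under 0.05. At an unadjusted p under 0.05, 6 splits gave at least the 354 genes of the real one, and the highest other gave 2559. The 5 other splits that part 6 µM replicate 1 from 1000 µM replicate 3 gave 70 to 375. At an adjusted p under 0.05 the real split gave 0 genes, which all 10 splits reach by definition, so that count tests nothing, and the highest other gave 0. The split with 2559 genes set 6 µM replicate 1, 1000 µM replicate 1 and 1000 µM replicate 3 against the rest. This points to a structure of the samples other than the labelled manganese level. The split equals an exchange of labels between 6 µM replicate 1 and 1000 µM replicate 2, as a single mislabelled library would leave unequal groups. Mislabelling stays open as its source. Exchanging 6 µM replicate 1 with 1000 µM replicate 3, the pair that stood apart, gave 89 genes at an unadjusted p under 0.05, against 354 as labelled. With the first residual component of each split as a covariate, the real split gave 21 genes at the adjusted threshold and the highest other gave 1261. The 4 splits with that pair of libraries on the same side gave 11 to 1261 under it, and the 5 other splits that part the pair gave 0.

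The 5 lower genes on chromosome 11 were set against random placement. In 3 of 10000 random sets of 44 tested genes, some window of the same width (341626 bp) held at least 5 members, a permutation p of 0.00040, where the random median was 2. The window's width was set by these genes, so this p is too small and random placement stays open. Loss of the whole segment is argued against by the median log2 difference of -0.0020 over its 33 other tested genes. Shorter losses that remove every copy of the lower genes from all cells would leave no reads of them. The 5 genes averaged 2.63 to 17.7 FPKM at 1000 µM, which argues against such losses unless reads came from similar copies. Shorter losses in part of the cells or copies were not tested and stay open. Reads shared between similar gene copies remain open, as no sequence was used here. Over the whole genome, 5 of the 44 lower genes, not all of them on chromosome 11, had another within 50 kb, where random sets had a median of 2 (permutation p = 0.0602).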
